A study of Mus musculus with 6 samples.

How the data were processed

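The series measured total RNA from lacrimal glands of 3 wild-type and 3 Eda-/- mice, each 13 weeks old. Per the labels' protocols, glands were frozen after dissection, RNA was extracted with beads and TRIzol and purified on columns, and directional libraries were made after removal of ribosomal RNA. The values are counts: the authors deposited 1 table of raw, whole-number counts of reads per gene, with a column per sample and no pooling of replicates. Per the submitters' processing notes, the tools were bcl2fastq, Trimmomatic, STAR, featureCounts and DESeq2 and the genome build was GRCm38.p5. Their versions, the annotation release, the strand setting of the counting, the treatment of reads that map to several places and any filters are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes are uncertain, and so are genes with near-identical copies. No read quality or alignment was available, and the work began from the counts.

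Groups came from the genotype label and replicate numbers from the sample titles; columns were matched to samples by name, and 0 columns of per-sample values were left unmatched. The series' design text calls the samples of a condition biological replicates. Gene symbols, biotypes and coordinates were taken from GENCODE M21 (GRCm38) by gene identifier. Of the identifiers 50462 matched, 45823 with the same version, and 224 did not. Library totals ran from 11894395 to 15700899 counts. Exact binomial intervals and floors cover counting error only, since counts were summed over the libraries of a group. Reads carry no molecular identifiers.

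Genes were tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Genes were kept by filterByExpr with its defaults (minimum count 10), which left 13178, holding at least 99.7% of each library's counts. Libraries were scaled by TMM, and the model had genotype alone. Quasi-likelihood fits were robust, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The common biological coefficient of variation was 0.103. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values are scaled by TMM, and means are given with SD over 3 libraries. Where a group held 1 to 3 counts, the ratio of normalised counts is given with an exact binomial (Clopper-Pearson) 95% interval; where it held 0, the fold is a lower bound from a floor of 3 counts over the group.

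Before the data were examined, 34 gene lists of pathways and cell types were fixed, together with the design, the main alternatives and the rule for naming genes. A further set of sex-linked genes was read per library and not tested as a list. The lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 27 lists with 5 or more tested members. The 7 others (salivary gland, mucins, skeletal muscle, keratinised epidermis, T and NK cells, B cells, neutrophils and mast cells) had fewer. Counts of passing members are given over all tested genes and adjusted over the list alone. Camera with an estimated correlation and fry were run beside the main list test.

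The rule named Eda, Edar, Eda2r and Edaradd; then, among genes that passed, did not overlap between groups, had a mean of at least 1 CPM and were neither predicted genes nor pseudogenes, the 10 highest and 10 lowest fold changes and the 5 smallest p-values in each direction; then up to 4 passing members of each list by p; and up to 4 of each symbol family with 5 or more passing members. For a called list with no passing member, 3 members are given as values. Outside the rule, Mucl2, Irf7, Igha, Glo1, Alad, Hdhd3, Rela, Traf1, Tnfrsf19, Wnt5b, Aldh1a3, Scgb2b24, Scgb2b33, Krt5, Krt14, Krt17 and Acta2 were chosen after their values were seen. The WNT members Axin2, Lgr4, Myc and Znrf3 were also chosen after their values were seen. Not every gene that the rule names is reported here.

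Replicate libraries were compared by a chi-square of their counts, which found no pair that agreed within sampling noise. Alternatives tried were DESeq2 1.42.0, limma-voom without and with sample weights, other scalings (DESeq2 size factors, library totals, upper quartile), other filters on low counts, removal of the 20 most abundant genes or of mitochondrial, ribosomal and small RNA genes, a replicate block, a test against a 1.2-fold change, fits that were not robust, and each library left out in turn. Added after the data were seen were removal of genes in clustered windows, removal of genes sharing 10% or more of their 31-base words with another gene, removal of a trend on GC content and length (available for 99.8% of tested genes), the EDA pathway list without Eda, and list counts and differences between list medians without each library.

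The scripts were first tested on simulated counts for the 13178 genes with the real library sizes, of which 12924 passed the filter again. In the simulation 200 genes were changed, and a list of 25 further genes was shifted 1.5-fold. Genes changed 1.5-fold were recovered in 62.3% of 61 cases, 2-fold in 83.1% of 77 and 4-fold in 94.1% of 51, and 6.7% of calls were unchanged genes. Simulated genes vary independently of each other, which real genes do not. The simulated list of 25 shifted genes had a camera adjusted p of 6.67e-31, and the 2 unchanged lists had 0.238 or more. A test of neighbouring genes called 1 of 20 random gene sets.

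Sharing of 31-base words was computed from the longest GENCODE M21 transcript of each gene. Clustering of large-fold genes was tested by counting pairs of genes of different symbol stems 0.5 to 5 Mb apart and comparing with 10000 random sets of tested genes. Figures were drawn with matplotlib.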

Results

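RNA was sequenced from lacrimal glands, the exocrine glands that secrete the watery part of the tear film, of adult mice 13 weeks old. The 6 libraries fell into 2 groups of 3 biological replicates: wild-type glands, and glands of Eda-/- mice, titled Tabby in the labels. Eda encodes ectodysplasin A, a ligand of the TNF family that acts through the receptor Edar and NF-kB in the development of hair, teeth and exocrine glands. All 6 samples carried the same C57BL/6 strain label. The deposited table held raw read counts per gene, with 14895607, 15700899 and 13670343 counts in wild-type 1, 2 and 3 and 12247077, 11894395 and 14480331 in mutant 1, 2 and 3. Of its genes 15583 had 0 counts in every library and 13178 were tested. All 6 libraries held 194 or more counts from each of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty and at most 3 counts from Xist.

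The comparison asked how the gland transcriptome differed without ectodysplasin A. Eda itself (ENSMUSG00000059327.9, GRCm38 chromosome X, 99975606 to 100400762, plus strand) had 41, 48 and 42 counts in the wild-type libraries and 2, 0 and 0 in the mutants, a ratio of 47.1 with a 95% exact binomial interval of 12.8 to 393 that covers counting error only. Among the genes that fell were the NF-kB inhibitors Nfkbia and Tnfaip3, the retinoic acid enzyme Aldh1a1, the contractile kinase Mylk, the basal transcription factor Trp63 and the macrophage genes Tyrobp and Csf1r. The abundant secreted mucin-like gene Mucl2 rose, as did the chaperone Creld2 and the respiratory chain subunit Sdhb. Of 29 tested secretoglobin genes 8 rose and 3, all annotated as pseudogenes, fell. In numbers, 1728 of 13178 genes passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05), 819 higher and 909 lower in the mutant. Of the genes that passed, 538 had more than a 2-fold change, 168 higher and 370 lower. Genes with any counts numbered 24637, 24681 and 26240 in the wild-type libraries and 22380, 22416 and 21897 in the mutants. This did not follow library totals alone, as wild-type 3 had fewer total counts than mutant 3. Whether it contributes to the excess of large decreases was not tested.

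**Figure D1:**
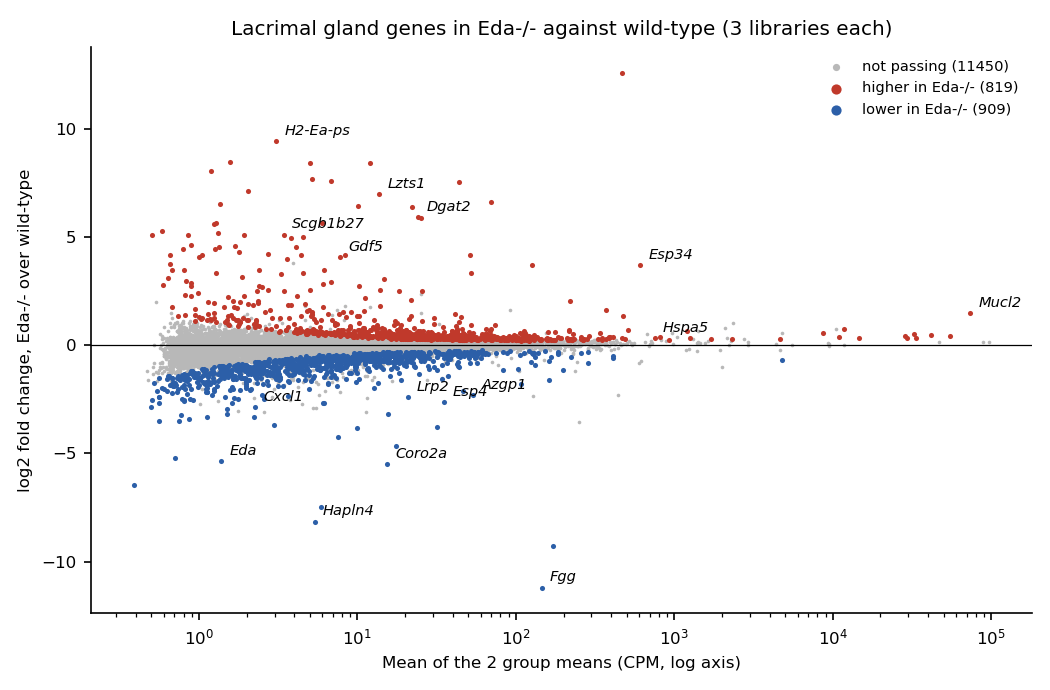
Fitted log2 fold change (mutant over wild-type) of each of the 13178 tested genes against the mean of both group means in CPM (read counts normalised to library size), with the 819 genes that passed higher in red and the 909 that passed lower in blue. Fgg lies lowest at -11.20 and Mucl2 is the most abundant gene that passed; the fitted value of H2-Ea-ps, at 0 counts in wild-type, depends on the prior count and is no bound.

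The first principal component of log2 CPM held 62.7% of the variance and placed the wild-type libraries at -38.60 to -29.22 and the mutants at 31.68 to 33.05. Within groups, pairs of libraries differed by more than sampling noise, with chi-square per degree of freedom between 9.08 and 28.9. In 1717 of the 1728 genes the 3 mutant libraries all lay on one side of the 3 wild-type libraries. Such separation was found in 32.1% of all tested genes, where chance gives 10%. The number of lower genes was 599 without mutant 3. With library totals in place of the trimmed mean of M-values (TMM), 246 genes were higher and 4365 lower, because the median gene then lay at -0.28 (log2); after a trend on GC content and length was removed, 1434 were higher and 846 lower.

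Some genes of NF-kB signalling fell in the Eda-/- glands, and most members of the pathway list did not pass. Nfkbia, the inhibitor that holds NF-kB in the cytoplasm, fell from 40.8 ± 8.71 to 20.4 ± 1.47 CPM (SD, n = 3 each; log2 fold change -0.998, SE 0.14, edgeR adjusted p = 0.00108). Tnfaip3, which encodes the deubiquitinase A20 that ends NF-kB signalling, fell from 7.68 ± 2.79 to 2.47 ± 0.214 CPM (-1.63, SE 0.26, adjusted p = 0.00137). Relb, an NF-kB subunit, fell by 1.16 on the log2 scale. Wild-type 3 had the highest CPM of Nfkbia (50.8 against 35.2 and 36.4), Tnfaip3 (10.85 against 5.61 and 6.59) and Relb (10.59 against 6.42 and 7.18), and without it they fell by 0.80, 1.30 and 0.91. Macrophage genes fell too (below), and which cells the NF-kB change came from was not tested. The subunit Rela (-0.52) and the adaptor Traf1 (-1.40) passed lower and the receptor Tnfrsf19 (0.95) higher, less firmly. Rela did not pass without wild-type 2 or 3 or any 1 mutant (adjusted p up to 0.217), and Traf1 without wild-type 1 or 3 or any 1 mutant (up to 0.129). Tnfrsf19 did not pass without wild-type 1 or 3 or mutant 1 or 3 (up to 0.0927). Edar had 7, 7 and 4 counts in wild-type and 1, 3 and 7 in the mutants, too few to be tested. The X-linked receptor Eda2r (-0.19, adjusted p = 0.602) and the Edar adaptor Edaradd (0.04, adjusted p = 0.873) did not pass. In the EDA pathway list 6 of 20 tested members fell and 1 rose, the same counts as adjusted over the list alone (median -0.13; camera adjusted p = 0.0215; adjusted p = 0.4 with an estimated correlation). That list includes Eda itself; with Eda left out, a choice made after the data were seen, the camera adjusted p was 0.06 and the median of the 19 others -0.08. Of 25 genes described as EDA targets in ectodermal organs, 17 were not tested, Shh and Lef1 among them. Among the 8 tested members 4 fell and none rose (5 fell adjusted over the list alone; median -0.73, camera adjusted p = 0.00141; adjusted p = 0.4 with an estimated correlation). The 4 were Nfkbia, Tnfaip3, Relb and the chemokine gene Cx3cl1 (-0.85), of which the first 3 also belong to the pathway list. Ccn2 (-0.61), Fst (-0.39), Ptch1 (-0.08) and Foxc1 (0.02) did not pass over all tested genes. In the pathway list the median was -0.05 without wild-type 3 and -0.07 without mutant 1.

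**Figure D2:**
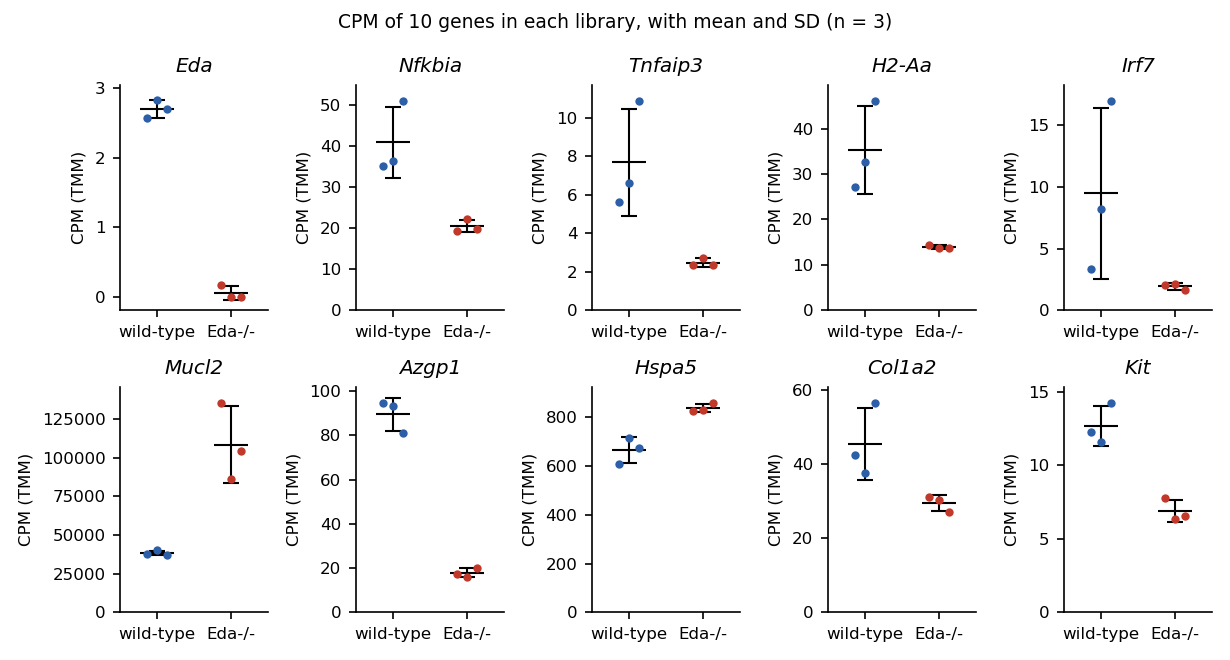
CPM (TMM-scaled) of 10 genes in each library; points are libraries, horizontal lines the group means and bars the SD (n = 3 per group). Irf7, which did not pass in edgeR, spanned 3.30 to 16.95 CPM among the wild-type libraries and 1.64 to 2.16 among the mutants.

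The secreted products of the gland moved in both directions. Mucl2, chosen after its values were seen, rose from 4.23% ± 0.14 of all counts in wild-type to 9.85% ± 2.52 in the mutants (SD, n = 3 each; log2 fold change 1.22 with library totals, and 1.49 after TMM scaling, SE 0.15, edgeR adjusted p = 0.000195). The 10 most abundant genes together held 49.1% ± 0.88 of wild-type and 54.6% ± 0.44 of mutant counts. Of 34 tested genes in the list of lacrimal secreted proteins, 10 rose and 4 fell (10 and 6 adjusted over the list alone), and the list was not called (camera adjusted p = 0.187). Scgb1b27 and Scgb2b27, secretoglobins encoded side by side on chromosome 7, rose by 5.11 and 3.47 (log2), and the far more abundant Scgb2b24 rose by 0.50. Scgb2b1, Scgb2b28-ps and Scgb2b33, annotated as pseudogenes, fell by 2.13, 1.80 and 4.67 (log2), the last not passing without wild-type 2 or 3 or any 1 mutant. Azgp1, which encodes zinc-alpha-2-glycoprotein, fell from 89.5 ± 7.44 to 17.9 ± 1.99 CPM (-2.32, SE 0.10, adjusted p = 1.58e-10). The exocrine gland-secreted peptide gene Esp4 fell by 2.64 (log2), and Esp3 fell by 3.79. From the same family, Esp34 and Esp38 rose by 3.72 and 2.05. These Esp genes lie in windows of clustered large changes on chromosome 17 (below). Scgb1b27, Scgb2b27, Scgb2b1, Scgb2b28-ps and Scgb2b33 lie in such a window on chromosome 7. Whether a genetic difference between the mice there altered these counts was not tested. Secretoglobin genes share on average 41.1% of their 31-base words with other genes and Esp genes 12.5%. Reads of members that share many words can be assigned to the wrong copy, and such values are uncertain. Scgb1b27 (4.6%), Scgb2b27 (6.5%), Esp3 (4.6%) and Esp4 (0%) share few, so this concern is smaller for them.

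Of the acinar secretory machinery, 7 of 29 tested genes rose and 1 fell (8 and 2 adjusted over the list alone; not called, camera adjusted p = 0.354). Itpr3, a calcium release channel of the endoplasmic reticulum, rose by 0.43 and Bhlha15 (Mist1), a transcription factor of serous secretory cells, by 0.36. Stim1, the calcium sensor of store-operated entry, rose by 0.41, and the granule GTPase gene Rab26 fell by 0.60. Of the acinar genes 4 rose without wild-type 1, wild-type 2, mutant 1 or mutant 3, and 2 fell without wild-type 1 or 3 and 3 without mutant 1 or 2. Of 28 tested genes in the list of protein folding in the endoplasmic reticulum, 8 rose and none fell (9 adjusted over the list alone; median 0.16, camera adjusted p = 0.00264; adjusted p = 0.4 with an estimated correlation). Creld2 rose by 0.61, Hyou1 by 0.42 and Hspa5, the chaperone BiP, from 667 ± 54.3 to 838 ± 16.3 CPM (log2 0.33, SE 0.08, adjusted p = 0.0139). Hspa5 did not pass without wild-type 1 or mutant 3. Of the nuclear-encoded respiratory chain, 5 of 32 rose and none fell (9 adjusted over the list alone; median 0.19, camera adjusted p = 1.32e-05; adjusted p = 0.4 with an estimated correlation), among them the complex II subunit Sdhb (0.55) and the complex I subunit Ndufv1 (0.30). Of 7 tested mitochondrially encoded genes 0 passed in edgeR, at an unadjusted p under 0.05, in DESeq2 or in limma-voom (median 0.05, camera adjusted p = 0.714). Their median was 0.127 without wild-type 3, 0.109 without mutant 1, 0 without wild-type 2 and -0.236 with library totals. All genes of the mitochondrial chromosome together held 0.46% ± 0.03 of wild-type and 0.36% ± 0.03 of mutant counts (SD, n = 3 each). With library totals in place of TMM, the medians of the secreted protein, acinar machinery, protein folding and respiratory chain lists were -0.14, -0.24, -0.12 and -0.09. The number of protein folding genes that rose was 5 without wild-type 1 or wild-type 3 and 4 without mutant 3; of respiratory chain genes it was 3 without wild-type 1 and 1 without wild-type 2 or mutant 1.

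Several macrophage genes fell, and few interferon response genes passed. In the macrophage and dendritic cell list 8 of 22 tested members fell and none rose (20 adjusted over the list alone; median -1.05, camera adjusted p = 7.7e-09; adjusted p = 0.4 with an estimated correlation). H2-Aa, an MHC class II chain, fell from 35.3 ± 9.70 to 13.96 ± 0.388 CPM (-1.34, SE 0.20, adjusted p = 0.00452), and did not pass without mutant 1. The signalling adaptor Tyrobp, the mannose receptor Mrc1 and Csf1r, the receptor of macrophage colony-stimulating factor, fell by 1.71, 0.93 and 1.01 on the log2 scale. H2-Aa lies on chromosome 17 at 34282744 to 34287823, in a window with many large changes that also holds H2-Ea-ps (below). Tyrobp and the passing members C1qa and C1qc also lie in windows of clustered large changes. Whether a genetic difference between the mice at these places altered the counts was not tested. Members that fell numbered 13 without wild-type 1 or wild-type 3, and 3, 5 and 4 without mutant 1, 2 and 3. Of 29 tested interferon response genes 28 had values below 0 (median -1.47, camera adjusted p = 2.61e-07; adjusted p = 0.457 with an estimated correlation), but 1, the GTPase gene Gbp6 (-3.40), passed the gene test, the same count as adjusted over the list alone. At an unadjusted p under 0.05 it was 17, and DESeq2 passed 15, Irf7 among them, limma-voom 2 and limma-voom with sample weights 3. Gbp6 shares 58.7% of its 31-base words with other genes and lies in a window of clustered large changes on chromosome 5. Relative to the wild-type mean, the list's mean log2 CPM was -0.84, -0.06 and 0.91 in wild-type 1, 2 and 3 and -1.15, -1.11 and -1.49 in the mutants. Its median was -0.79 without wild-type 3, and 21, 2, 8, 0 and 3 members passed without wild-type 1, 2 and 3 and mutant 1 and 2. Wild-type 3 also lay above the other wild-type libraries in further called lists, among them macrophage (0.49 against -0.27 and -0.22), cytokine (0.49 against -0.28 and -0.21) and matrix (0.36 against -0.18 and -0.17). The same held for cell cycle (0.36 against -0.31 and -0.05), immediate early (0.29 against -0.16 and -0.13) and myoepithelial genes (0.23 against -0.13 and -0.10). Of 12 tested cytokine, chemokine and adhesion genes 3 fell and none rose (3 adjusted over the list alone; median -0.65, camera adjusted p = 0.0167; adjusted p = 0.434 with an estimated correlation). These were the neutrophil chemokine Cxcl1 (-2.85), the adhesion molecule Vcam1 (-2.06) and the chemokine Cxcl16 (-1.25). Cxcl1 also lies in a window of clustered large changes. Without mutant 1 or mutant 3, Vcam1 and Cxcl16 did not pass and 1 member did. The cytokine list had a camera adjusted p of 0.0559 without mutant 1, and medians of -0.35 without wild-type 3 and -0.29 without mutant 3.

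**Figure D3:**
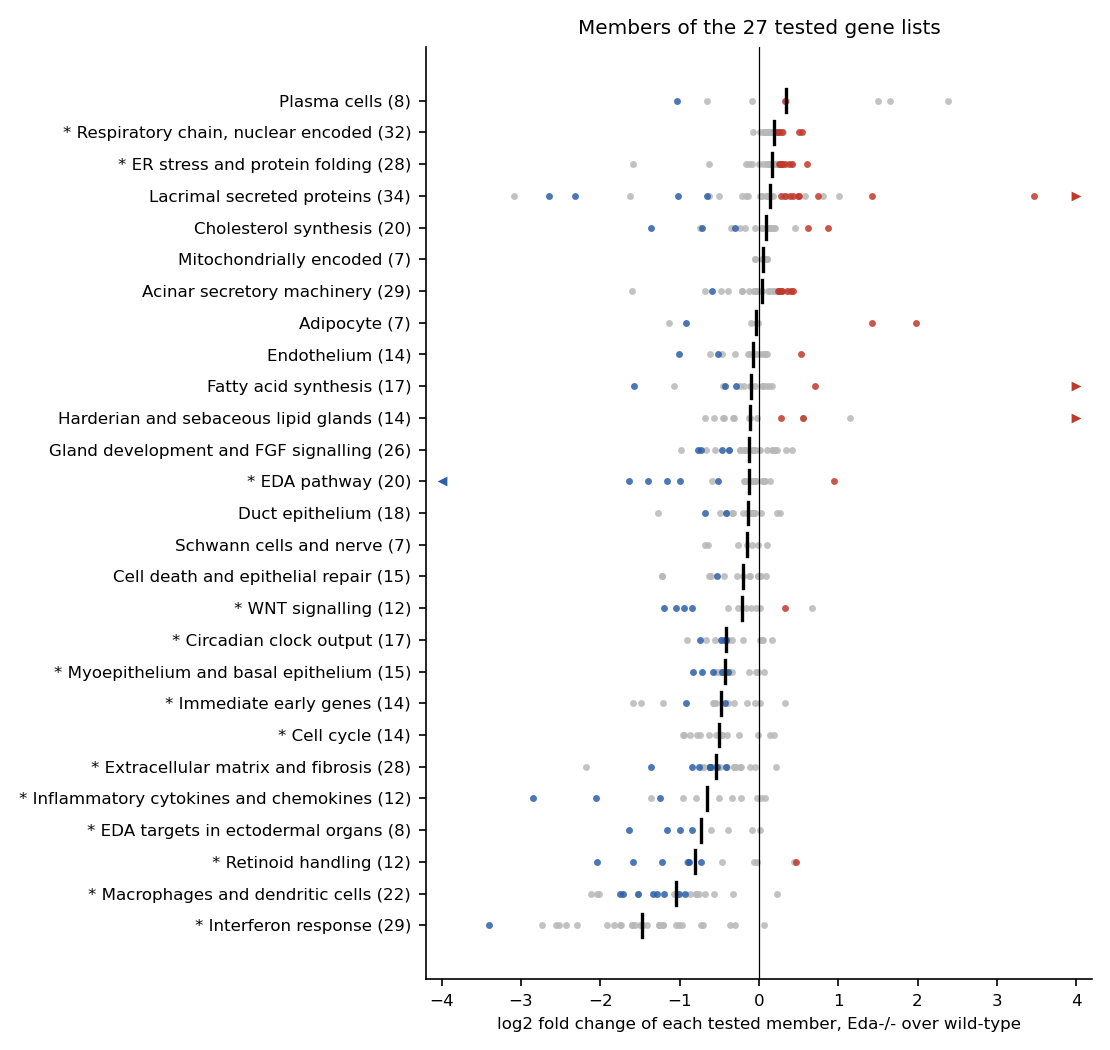
Log2 fold change (mutant over wild-type) of each tested member of the 27 gene lists with 5 or more tested members (number in parentheses). Points are genes, red and blue where they passed higher or lower and grey where they did not, arrowheads mark values beyond 4, black bars are medians and asterisks mark the 14 lists called by camera; medians ran from -1.47 (interferon response) to 0.34 (plasma cells, not called).

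Some matrix and myoepithelial genes fell as well. In the extracellular matrix list 8 of 28 tested genes fell and none rose (13 adjusted over the list alone; median -0.54, camera adjusted p = 2.23e-06; adjusted p = 0.4 with an estimated correlation). The matrix protease Mmp2 fell by 0.84, the decorin gene Dcn by 0.42, and the type I collagen chain gene Col1a2 from 45.4 ± 9.75 to 29.6 ± 2.14 CPM (-0.62, SE 0.14, adjusted p = 0.0196). Col1a2 did not pass when any 1 mutant was left out. The matrix median was -0.31 without wild-type 3, and 4, 5 and 4 members fell without mutant 1, 2 and 3. Of 15 myoepithelial and basal genes 5 fell and none rose (8 adjusted over the list alone; median -0.43, camera adjusted p = 0.00118; adjusted p = 0.4 with an estimated correlation). Among them were Mylk (-0.71), the kinase that activates smooth muscle myosin, and Trp63 (-0.83), a transcription factor of basal epithelial cells. The basal keratins Krt5 (-0.03), Krt14 (-0.01) and Krt17 (0.07) did not pass, nor did the smooth muscle actin Acta2 in edgeR (-0.54, adjusted p = 0.142; 0.0262 in DESeq2). This list's median was -0.23 without wild-type 3, and 3 members fell without wild-type 2, mutant 1 or mutant 2 and 2 without wild-type 3 or mutant 3. Of 14 endothelial genes Vwf (-1.01) and Flt1 (-0.51) fell and Plvap rose (0.53), counts that were the same adjusted over the list alone, and the list was not called (median -0.07, camera adjusted p = 0.277). With each library left out in turn, 2 endothelial genes fell and none rose. The endothelial median was -0.27 without mutant 1 and 0.01 without mutant 3.

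Several signalling lists were called lower by camera. Of 12 tested genes of retinoid handling 6 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.80, camera adjusted p = 0.00264; adjusted p = 0.4 with an estimated correlation). The retinaldehyde dehydrogenases Aldh1a1, Aldh1a2 and Aldh1a3, which make retinoic acid, fell by 0.90, 2.04 and 1.22 (log2), the binding protein gene Crabp1 fell by 1.59, and the retinaldehyde reductase Dhrs3 rose by 0.46; 3 members fell without wild-type 3 or mutant 2. Aldh1a2 did not pass without wild-type 3, mutant 2 or mutant 3, and Aldh1a3 without wild-type 2 or 3 or any 1 mutant. In the WNT list the secreted regulator Dkk3 (-1.04), the ligands Wnt4 (-1.19) and Wnt5b (-0.95) and the cyclin Ccnd1 (-0.84) fell and the ubiquitin ligase Rnf43 rose (0.33), 4 and 1 of 12 and the same counts adjusted over the list alone (median -0.21, camera adjusted p = 0.0215; adjusted p = 0.4 with an estimated correlation). Of the 31 WNT genes listed 19 were not tested. The 7 other tested members did not pass, among them Axin2 (0.01), Myc (-0.03), Lgr4 (-0.10) and Znrf3 (-0.39). The WNT list had a camera adjusted p of 0.116 and a median of -0.13 without mutant 2. Its median was -0.14 without wild-type 3, and 2 members fell without mutant 3. Wnt5b did not pass without wild-type 1 or 2 or any 1 mutant, Wnt4 without mutant 3, or Rnf43 without wild-type 1 or 2 or mutant 1 or 3. Of 17 circadian clock genes 4 fell, among them the period genes Per2 (-0.74) and Per3 (-0.42), and none rose (5 adjusted over the list alone; median -0.42, camera adjusted p = 0.00737; adjusted p = 0.4 with an estimated correlation). Of the clock genes 1 fell without wild-type 2, and 2 without wild-type 3 or mutant 3; Per3 did not pass without wild-type 2. The immediate early genes Nr4a2 (-0.92) and Junb (-0.42) fell, 2 of 14 (4 adjusted over the list alone; median -0.48, camera adjusted p = 0.00673; adjusted p = 0.4 with an estimated correlation). Without wild-type 3 the immediate early list had a camera adjusted p of 0.0683 and a median of -0.26, and 1 member fell without wild-type 1, mutant 1, mutant 2 or mutant 3. Junb did not pass without wild-type 1 or 3 or any 1 mutant. Of 14 cell cycle genes 0 passed in edgeR, over all genes or adjusted over the list alone, and 6 had an unadjusted p under 0.05; DESeq2 passed 2 and limma-voom 0 (median -0.51, camera adjusted p = 0.0219; adjusted p = 0.518 with an estimated correlation); Mcm2, Mcm4 and Mcm6, helicase subunits of DNA replication, had values of -0.40, -0.46 and -0.96. The cell cycle camera adjusted p was 0.141 without wild-type 3, the median -0.82 without wild-type 1 and -0.78 without mutant 1, and 5, 1, 2, 2 and 1 members passed without wild-type 1 and 2 and mutant 1, 2 and 3.

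Of the 27 lists with enough tested members, camera with a preset correlation of 0.01 called 14, 2 higher and 12 lower. With the correlation estimated from the 6 libraries it called 0, and 2 lists had an unadjusted p under 0.05. With fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, 5 passed: the EDA pathway, EDA target, retinoid, WNT and respiratory chain lists. The EDA pathway list holds the mutated gene Eda itself, so its calls rest partly on the genotype. With Eda left out its camera adjusted p was 0.06, and no fry value is given for that setting. Splits of the 6 libraries that mixed the genotypes also had up to 10 lists called by camera with the preset correlation (below).

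Some of the genes with extreme fold changes were nearly absent from 1 of the groups. Fgg, the gamma chain of fibrinogen (ENSMUSG00000033860.13, GRCm38 chromosome 3, 83007724 to 83015049, plus strand), fell from 291 ± 19.5 to 0.116 ± 0.202 CPM (SD, n = 3 each; log2 -11.20, SE 0.30, edgeR adjusted p = 4.95e-08). Hapln4, a hyaluronan link protein (ENSMUSG00000007594.10, chromosome 8, 70083457 to 70090862, plus strand), had 520 counts in wild-type against 1 in the mutants, a ratio of 374 (95% exact binomial interval 66.8 to 14800). The coronin gene Coro2a fell by 5.51, the glycine receptor subunit gene Glrb by 3.85 and the microtubule-associated gene Eml1 by 3.18 on the log2 scale. In the other direction, Lzts1, a leucine zipper gene (ENSMUSG00000036306.13, chromosome 8, 69132669 to 69184225, minus strand), rose from 0.206 ± 0.0383 to 27.1 ± 1.67 CPM (log2 6.98, SE 0.18, adjusted p = 5.03e-13). Dgat2, which makes triglycerides, rose by 5.92 (log2) and the growth factor gene Gdf5 by 4.08, though Gdf5 shares 39.7% of its 31-base words with other genes. The antibody heavy chain segment Ighv9-4 had 143 counts in the mutants and 1 in wild-type (ratio 199, interval 35.1 to 7910) and shares 29.6% of its words. Apobec2 had 97 and 1 (ratio 135, interval 23.7 to 5380). H2-Ea-ps, annotated as a polymorphic pseudogene of the MHC on chromosome 17 (34341959 to 34344645), had 0 counts in wild-type and 215 in the mutants. This was at least 99.7-fold higher against a floor of 3 counts over the group. Fgg, Hapln4, Glrb, Eml1, Gdf5, Ighv9-4, Apobec2 and H2-Ea-ps lie in windows of clustered large changes (below). Coro2a, Lzts1 and Dgat2 lie outside those windows. Whether these changes follow from loss of Eda or from another genetic difference was not tested.

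Large changes were mapped along the chromosomes. The 265 genes that passed with an absolute log2 fold change above 1.5 (110 higher, 155 lower) lay on 20 chromosomes, and 30 of the 282 windows of 10 Mb that held tested genes were picked for holding 3 or more of them. These windows held 140 of the 265, and 2477 of the 13178 tested genes. The fullest windows were on chromosome 17 at 30 to 40 Mb, with 14 such genes including H2-Q1, H2-Q10 and Esp34, and on chromosome 4 at 130 to 140 Mb, with 13 including Klhdc7a and Rps6ka1. The chromosome 4 window also held the immune genes Cd52, C1qa and C1qc. A window on chromosome 6 at 120 to 130 Mb held the immune genes Clec4a1, Clec7a and Klrk1. Without the genes of these windows, a setting added after the data were seen, 1101 genes passed, 523 higher and 578 lower. Of the 110 large increases, 36 (32.7%) were pseudogenes, against 235 (1.8%) of all tested genes (Fisher's exact test, two-sided, odds ratio 31.4, p = 2.95e-36). Of the 155 large decreases 9 (5.8%) were (odds ratio 3.49, Fisher's exact p = 0.00185). A gene nearly absent from 1 group, such as H2-Ea-ps, entered the tested set only through its counts in the other. Copies that share reads are also not independent, so these Fisher's exact p-values are no clean chance rates. Among ribosomal protein genes, Rps3a1 fell by 1.59 and Rpl21 by 0.79 (log2), and the pseudogenes Rps3a3 and Rpl3-ps1 rose by 4.15 and 4.16. Rps3a1 shares 76.9% of its 31-base words with other genes and Rps3a3 78.4%, Rpl3-ps1 97.4% and Rpl21 27.4%, so how reads split between such copies is uncertain.

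**Figure D4:**
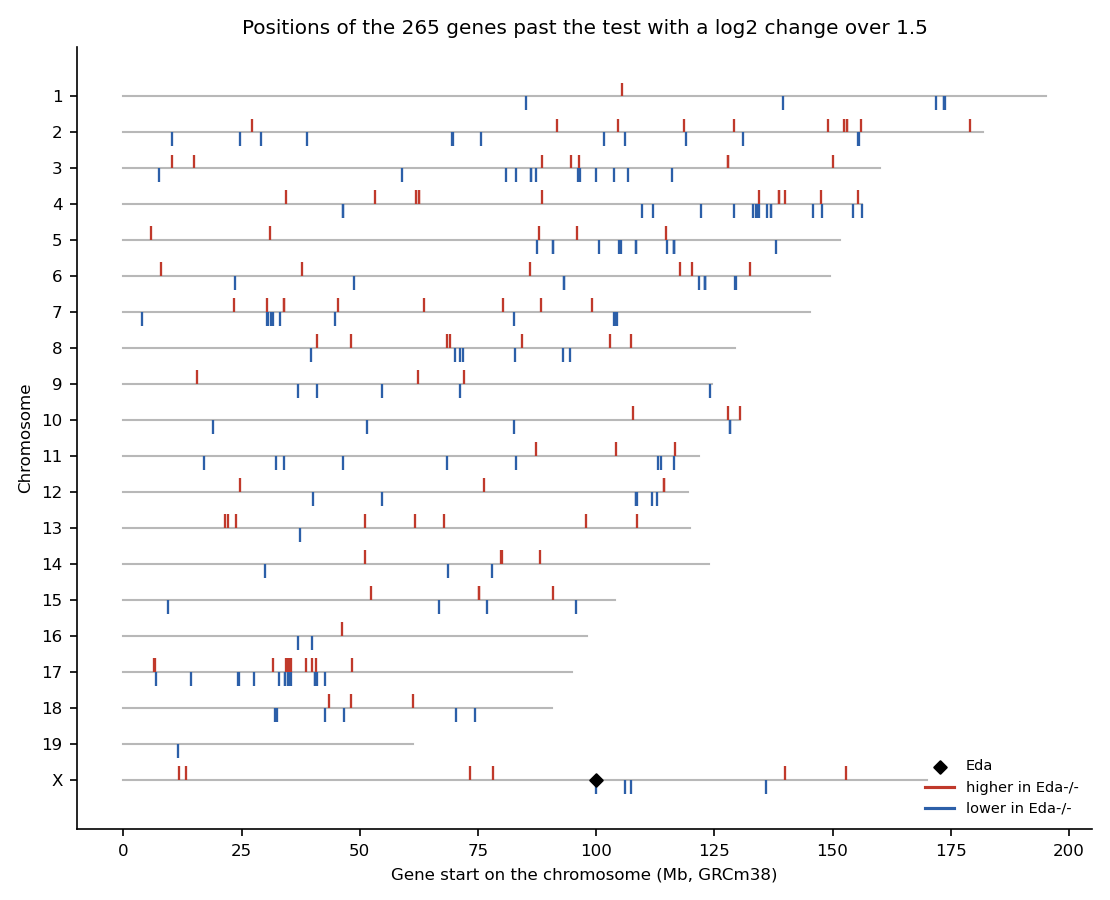
Start positions (Mb, GRCm38) of the 265 genes that passed with an absolute log2 fold change above 1.5 on chromosomes 1 to 19 and X; red marks above a line are genes higher in the mutant, blue marks below it lower ones, and the diamond is Eda. Marks fall on 20 chromosomes, with 14 in the window of chromosome 17 from 30 to 40 Mb.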

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

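Removal of clustered windows, of genes with shared 31-base words and of the GC and length trend, the EDA pathway list without Eda, and list counts and differences between list medians without each library, were chosen after the data were seen; the other settings were planned. Eda kept its direction and passed in all 22 fits that gave it a value. Across all settings, other named genes kept direction and side of the threshold in 4881 cases, lost the call in 543, gained it in 15 and reversed in 4. Losses were most under a test against a 1.2-fold change (94), without mutant 3 (58), with library totals (54) and in DESeq2 (53). The 4 reversals all came with library totals in place of TMM: Agps -0.002, Cox4i1 -0.024, Sec62 -0.007 and Eif4g1 -0.009. That setting gave 4611 changed genes, 246 higher (5.3%) and 4365 lower, against 47.4% higher with TMM. DESeq2 gave 593 lower genes, and 1008 of its 1169 calls were shared with edgeR. A test against a 1.2-fold change, which asks for more, gave 665 genes, 251 higher and 414 lower. Leaving out genes in clustered windows, which tests fewer genes, gave 1101, 523 higher and 578 lower. Removing the GC and length trend gave 1434 higher genes, 62.9% of calls; the cause was not tested. Without single libraries, lower genes ranged from 599 to 834, with fewer samples in each fit.

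The lists depended more on the test. With an estimated correlation 0 lists were called: adjusted p was 0.4 for the EDA pathway, EDA targets, myoepithelium, retinoid, macrophage, matrix, WNT, protein folding, circadian, immediate early and respiratory chain lists, 0.457 for interferon (0.373, 0.528 and 0.474 without wild-type 1, 2 and 3), 0.434 for cytokines and 0.518 for cell cycle. With fry 5 lists were called, and adjusted p was 0.098 for myoepithelium, 0.052 for macrophages, protein folding and circadian, 0.134 for interferon, 0.106 for cytokines, 0.0918 for matrix and immediate early and 0.2 for cell cycle. With library totals, camera adjusted p was 0.221 for cytokines, 0.0991 for WNT, 0.308 for cell cycle, 0.0559 for protein folding and 0.133 for immediate early genes, and 0.0198 for secreted proteins and for plasma cells. Cell death had 0.0498 with a prior count of 0.5, and 0.0463 without clustered windows, where duct had 0.00917, plasma cells 0.027 and WNT 0.0502. With the GC and length trend removed duct had 0.0193 and cell death 0.0269. The EDA pathway list without Eda had 0.06. Without single libraries camera adjusted p ranged from 0.0267 to 0.155 for cell death, 0.0174 to 0.27 for duct, 3.83e-05 to 0.141 for cell cycle, 0.0027 to 0.0683 for immediate early genes, 0.00676 to 0.0559 for cytokines, 0.046 to 0.686 for plasma cells and 0.0241 to 0.116 for WNT. The cause of these changes was not tested.

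The labels do not say that equal replicate numbers mark a shared litter or day, and deviations of same-numbered libraries from their group means correlated across genes at -0.035, 0.021 and -0.094, no more than those of other pairs (-0.048 to 0.077). The samples were not treated as pairs. With the replicate number as a block, 1608 genes changed, 712 higher and 896 lower, and duct (0.0308) and cell death (0.0369) were called. A fit with sex as a covariate was not run because all 6 libraries held Y-linked reads and at most 3 Xist counts, although Y-linked counts varied, as with Eif2s3y (194 to 543). At this depth genes with a few counts per library, Edar among them, could not be tested.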

Other observations

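In this part, the tests of genome differences, of a segment on the X chromosome, of wild-type 3, of macrophage number, of acinar share and of scaling relative to all tested genes were chosen after the results were seen. Lists not described above were mixed or small. Of 26 tested genes of gland development 4 fell, the transcription factors Runx1 (-0.77), Sox10 (-0.73) and Barx2 (-0.47) and the receptor Fgfr1 (-0.38), and none rose (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.204). Of these 1 fell without wild-type 1, wild-type 2, mutant 2 or mutant 3 and 2 without wild-type 3. Of 18 duct genes the bicarbonate transporter Slc4a4 (-0.68) and the cadherin Cdh1 (-0.42) fell (2 adjusted over the list alone; camera adjusted p = 0.0585, and 0.0174, 0.0462 and 0.0362 without wild-type 2, mutant 1 and mutant 3). Kit, a receptor of mast cells and other cell types, fell by 0.87, Il7r, a receptor of T cells, fell by 2.55 and the muscle gene Mb (35.2% of 31-base words shared) fell by 2.03, each the single passing member of a list too small to test. Of 3 mucin-related genes Agr2 rose (0.39) and Spdef fell (-0.81), the latter not without wild-type 3, mutant 1 or mutant 2.

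In the plasma cell list Derl3 rose (0.33) and Slamf7 fell (-1.03) of 8 tested (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.266, and 0.046 without mutant 2). Slamf7 did not pass without wild-type 2 or 3 or mutant 2 or 3, nor Derl3 without mutant 3. The antibody gene Igha, chosen after its values were seen, had 24.2, 90.1 and 19.2 CPM in wild-type and 205, 81.4 and 133 in the mutants and did not pass in edgeR (adjusted p = 0.288), though it did in limma-voom (0.0242). Of 14 Harderian and sebaceous genes Dgat2 (5.92), Mc5r (0.55) and Agps (0.28) rose, though Agps passed without wild-type 3 and in no other fit with a library left out, and Mc5r did not pass without mutant 3 (5 adjusted over the list alone; camera adjusted p = 0.803). In fatty acid synthesis 2 of 17 rose and 3 fell (2 and 4 adjusted over the list alone; 0.58), in cholesterol synthesis 2 and 3 of 20 (3 and 3; 0.803), in the adipocyte list 2 and 1 of 7 (2 and 1; 0.872). In these 3 lists the counts were 0 to 2 in each direction with any 1 library left out. Anxa1 fell (-0.53), 1 of 15 cell death and repair genes (1 adjusted over the list alone; 0.0511, and 0.0352, 0.0267, 0.0462 and 0.0427 without wild-type 1, wild-type 2, mutant 1 and mutant 3). Anxa1 did not pass without wild-type 2 or 3 or mutant 1 or 3. Of 7 Schwann cell genes 0 passed in edgeR, DESeq2 or limma-voom and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.245). Median, mean and test differed in sign for the acinar, Harderian, adipocyte, cholesterol and fatty acid lists, none of them called. The salivary (1 tested gene), epidermal (1) and B cell lists had no passing member.

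Of the 10 splits of the 6 libraries into 3 against 3, 1, the real one, gave as many changed genes (1728, highest other 0) and 1 gave as many called lists (14, highest other 10). With 10 splits the share cannot be under 0.05. Splits that mixed the genotypes called 0 genes each, yet camera with the preset correlation called 1 to 10 lists in them. Such splits keep part of the genotype difference, so they show no clean background rate. A list called with the preset correlation is thus weak support by itself.

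Large changes lay close together on many chromosomes: 281 pairs of large-fold genes of different symbol stems were 0.5 to 5 Mb apart, against a mean of 159.9 and a maximum of 230 in 10000 random sets (permutation p = 1e-04, the smallest these can give). Shared reads are argued against as the whole cause, since 36.6% of the large-fold genes share 10% or more of their 31-base words (20.6% of tested genes) and the other 168 still gave 133 pairs (random maximum 113), and a segment carried along with Eda is argued against because 3.8% of them lie on the X chromosome. A candidate explanation is that the mutant and wild-type mice differ in genetic background beyond Eda, although all carry a C57BL/6 label. C57BL/6 mice are known not to transcribe H2-Ea, and H2-Ea-ps was seen in every mutant and no wild-type library; Glo1 (1.22), Alad (1.83) and its neighbour Hdhd3 (2.03), chosen after their values were seen, lie in segments known to be duplicated in some inbred strains. Local co-regulation of neighbouring genes, such as the immune genes Cd52, C1qa and C1qc on chromosome 4, was not tested. Which changes follow from loss of Eda cannot be read from 1 mutant line.

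The interferon list was called lower by camera with 1 of 29 members passing in edgeR (adjusted p = 0.457 with an estimated correlation), and wild-type 1 (-0.84) lay nearer the mutants (-1.15, -1.11 and -1.49) than wild-type 3 (0.91). A high wild-type 3 stays open as an explanation: the median was -0.787 without it (-1.636 to -0.787 over the wild-type libraries left out; camera adjusted p = 2.67e-06), but the group difference in mean log2 CPM was then -0.80, with an interval over libraries of -1.85 to 0.25 (-2.69 to 0.19 with all 6). Fewer macrophages may contribute: the interferon median differed from the macrophage median by -0.42, with a bootstrap interval over genes of -0.73 to 0.05, which leaves this open. That difference was -0.07 without wild-type 3 (-0.38 to 0.29), -0.64 without wild-type 1 (-1.03 to -0.14) and -0.52 without mutant 2 (-0.79 to -0.02). An effect of the mice's exposure was not tested.

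The protein folding list was called higher and the matrix and macrophage lists lower (adjusted p = 0.4 each with an estimated correlation). Scaling moves all genes of a library alike, so by construction it drops out of differences from the median of all tested genes. These differences were 0.16 for protein folding (bootstrap interval over genes 0.11 to 0.26), -0.54 for matrix (-0.62 to -0.41) and -1.05 for macrophages (-1.43 to -0.84). The intervals over genes also left out 0 without each library in turn. They treat genes as independent, although the estimated correlations within these lists were 0.161, 0.433 and 0.553. Over libraries the intervals of the mean differences were 0 to 0.28, -0.94 to 0.01 and -1.66 to -0.31. Without mutant 3 they were -0.08 to 0.34, -1.09 to 0.26 and -1.86 to 0.04, so these differences are less firm between mice. With library totals protein folding was not called (camera adjusted p = 0.0559). Scaling may still set the level: the protein folding median was -0.12 with library totals and the matrix and macrophage medians at most -0.53, but the median of all tested genes moved alike, from 0.003 to -0.277, and no scaling run put it above 0.01. A larger share of acinar cells would lower other cell types alike and is argued against as the whole cause for macrophage genes, whose median lay -0.97 from the endothelial one (-1.40 to -0.58; over libraries -1.41 to -0.33); for matrix genes (-0.46, -0.64 to -0.11) it stays open, as the interval reached 0.06 without wild-type 3 and 0.03 without mutant 2.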
